A study of Mus musculus domesticus with 100 samples.

How the data were processed

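The data were 100 bulk RNA sequencing libraries of 20 groups, each of 5 animals. Per the labels, RNA was extracted from snap-frozen tissue with Trizol for liver and with a lipid tissue kit for fat and hypothalamus, and polyadenylated RNA was made into TruSeq libraries read from both ends at 51 bases, a protocol that does not mark the strand of the transcript. According to the submitters' processing notes, reads were aligned with Bowtie 1.1.1 to transcripts of the mouse genome build GRCm38 (mm10) and quantified with RSEM 1.2.21. The expected count values were made by the authors with RSEM, which divides reads that fit several transcripts by their estimated abundance. The TPM values were made by the authors with RSEM, scaled by effective length to a common total within each library. The FPKM values were also made by the authors with RSEM and were described here but not used for any test. The effective length values, per gene and library, came from the same deposited RSEM output. Totals, detected genes and the relation between the units were checked in every library before any test.

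The gene tables held 25097 genes, of which 24746 were matched to a symbol and coordinates and 351 were not; the unmatched genes carried 0.088% of the counts. There were 3 symbols shared by 2 identifiers each, which were kept apart. Gene coordinates are GRCm38. Expected counts were rounded to whole numbers. Replicate numbers follow the order of the deposited libraries only.

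Each condition of 20 libraries was fitted with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the 4 strain-by-sex groups, libraries were scaled by TMM, and the quasi-likelihood F test (estimateDisp, robust glmQLFit, glmQLFTest) was applied to the mean strain difference over the sexes, the strain-by-sex interaction (strain difference in males minus that in females) and the mean sex difference over the strains. The change of the strain difference with age was tested in a joint edgeR fit of the 60 liver libraries in 12 groups. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p given for a gene comes from edgeR. Genes that passed in all conditions with the same sign were counted among the genes tested in all. At unadjusted p under 0.05, 8444, 6405, 6180, 5253 and 8905 genes differed between the strains in the liver at E16.5, 2 weeks and 4 weeks, hypothalamus and fat. For the interaction these counts were 1686, 692, 1136, 679 and 3325, and for sex 3568, 521, 1605, 653 and 5363. The median absolute log2 difference of the genes that passed was 0.40, 0.51, 0.57, 0.42 and 0.46, and 777, 544, 554, 459 and 830 of them shared at least 20% of their sequence with another gene.

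The gene lists, 50 in number with 904 genes, were written from general knowledge, and 4 of their symbols were not in the gene tables. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on voom values of the tested genes, with the inter-gene correlation estimated from the data; a preset correlation of 0.01 and fry were alternatives. Member counts use the adjusted p over all genes, and "adjusted over the list alone" means a Benjamini-Hochberg adjustment within the list. Member counts are to be read beside the share of all tested genes that passed for strain. That share was 52.8%, 35.6% and 36.6% in the liver at E16.5, 2 weeks and 4 weeks, 22.3% in the hypothalamus and 54% in fat.

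Genes were named by a rule: in each strain comparison the 5 highest and 5 lowest log2 differences among genes with adjusted p under 0.05, mean log2 CPM of at least 3, the same sign in both sexes and no overlap of the strains within either sex, leaving out predicted genes, RIKEN clones and pseudogenes; 2 members of each list with the smallest adjusted p; key genes of growth and metabolism in any case; and the 5 smallest adjusted p of each interaction and sex difference. The text describes a part of the genes so named. Shared sequence was measured as the share of a gene's 31-base sequences that also occur in another gene, for 24744 genes with such sequences; 4251 genes shared at least 20%, and genes sharing at least 50% formed 760 families of 2170 genes. That share is given beside a named gene where it reached 20%. No fold is given where a strain was near 0 counts; levels are given instead, and such a level can also reflect reads of a strain that do not align to the reference.

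The tests, filters, lists, naming rule, key genes and the following other settings were chosen before the data were examined. These settings were RLE and upper-quartile scaling, no filter, a mean of at least 1 CPM in a group, DESeq2 1.42.0, limma voom with sample quality weights, an offset for effective length, limma-trend on log2 TPM, adjusted p under 0.01, at least a 2-fold difference, each library left out in turn, 1 fit of all 100 libraries, no near-absent genes, library size without the 20 most abundant genes, and a random block for the first characters of the embryo names, which may mark litters (correlation within blocks 0.00525). Chosen after the data were seen were fits without the 5 fat libraries highest in epithelial markers, without the 2 hypothalamus libraries highest in thalamus markers and without the 2 E16.5 libraries with the steepest GC trend, an offset for a smooth trend of each library on GC content and transcript length, and counts summed over gene families. In the TPM setting TMM was not applied and 1 was added before the log. No paired analysis was made, because the strains share no animals. The liver and hypothalamus at 4 weeks and the Gough fat came from the same animals, and the WSB fat from others.

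The steps were tested on simulated data drawn from negative binomial distributions with the fitted means, spread and library sizes, with known changes in 67, 67 and 66 genes at folds of 1.5, 2 and 4. The strain test recovered 74.6%, 92.5% and 98.5% of these at E16.5, 62.7%, 79.1% and 98.5% in the 2-week liver, 61.2%, 82.1% and 95.5% in the 4-week liver, 67.2%, 86.6% and 98.5% in the hypothalamus, and 76.1%, 89.6% and 95.5% in fat. The interaction test recovered 26.9%, 68.7% and 95.5%, then 6%, 46.3% and 81.8%, then 7.5%, 34.3% and 83.3%, then 29.9%, 64.2% and 92.4%, and 22.4%, 50.7% and 90.9%, in the same order of conditions. For sex the values were 76.1%, 91% and 100%, then 71.6%, 82.1% and 100%, then 62.7%, 88.1% and 95.5%, then 83.6%, 88.1% and 97%, and 64.2%, 77.6% and 95.5%. The change with age was recovered for 47.8%, 79.1% and 93.9% in the first step and 52.2%, 74.6% and 92.4% in the second. Between 2 and 12 unchanged genes were called per comparison. A list changed 1.5-fold was recovered in each condition by camera with an estimated correlation, but the simulated genes varied independently, which favours that test more than real tissue does. Within groups, 200 pairs of libraries were compared for duplication; the smallest chi-square per degree of freedom was 5.8 and the median 46.2, so no pair within a group was 1 library read a second time; pairs between groups were not compared. Tables were handled in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.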

Results

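Polyadenylated RNA was profiled in 100 libraries from Gough Island mice and from WSB mice. Gough Island mice are a large-bodied island population of the house mouse, and WSB is a wild-derived inbred strain of mainland origin. The organs were the left lobe of the liver in embryos of day E16.5, the liver at 2 weeks and at 4 weeks after birth, and the hypothalamus and the gonadal fat depot at 4 weeks. Each of these 5 conditions held 5 females and 5 males of each strain, 20 libraries in all. The design asked how expression in organs of growth and energy balance differs between the strains, whether the difference depends on sex, and whether it changes with age in the liver. The total expected count per library had a median of 25.4 M (M, mega) and reached 90.4 M. At E16.5 the Gough libraries held 18.3 to 38.5 M counts (median 21.8) and the WSB libraries 18.7 to 90.4 M (median 40.8). The medians in Gough and WSB were 23.7 and 31.3 M in the liver at 2 weeks, 22.4 and 19.4 M in the liver at 4 weeks, 18.4 and 27.0 M in the hypothalamus, and 27.2 and 25.8 M in fat. Between 15549 and 19484 genes were detected per library. Levels are given as CPM (counts scaled to a common library total), as mean ± SD with n = 10 per strain unless stated, and strain differences as log2 Gough minus WSB ± SE with the adjusted p of the edgeR quasi-likelihood test.

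In the E16.5 liver, genes of the insulin-like growth factor (IGF) system differed between the strains in opposite directions. Igfbp3 (chromosome 11, 7206086 to 7213923), which encodes the main IGF carrier of blood, stood at 47.4 ± 5.69 CPM in Gough and 12.7 ± 1.55 CPM in WSB, a log2 difference of 1.91 ± 0.08 (adjusted p = 4.78e-14). The strains did not overlap in either sex. Igf2 (chromosome 7, 142650766 to 142666816), the main fetal growth factor of the family, was lower in Gough by a log2 difference of -0.46 ± 0.08 (adjusted p = 6.96e-05). Its clearance receptor Igf2r was lower by -0.40 ± 0.07 (adjusted p = 0.00011). Igf1 was higher by 0.33 ± 0.07 (adjusted p = 0.000698), whereas Ghr, the growth hormone receptor, did not differ detectably (-0.01 ± 0.06, adjusted p = 0.886). Of the 20 tested members of the growth hormone and IGF list, 2 were higher, 9 were lower and 9 did not pass, and 12 passed when adjusted over the list alone. Among the lower members was Cish (-0.90 ± 0.10), a feedback inhibitor of cytokine signalling. Of all tested genes 52.8% passed at this age, so the share of this list that passed was near that of genes at large.

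The E16.5 livers also differed in their blood cell genes. The embryonic globin genes Hbb-bh1 (76.0 ± 31.9 against 8.97 ± 2.47 CPM, adjusted p = 2.26e-11) and Hbb-y (30.9 ± 24.8 against 3.53 ± 1.98 CPM, adjusted p = 3.02e-06), normally expressed in primitive red cells, were higher in Gough. The erythroid list as a whole did not share that direction. Of its members, 5 of 22 were higher, 10 were lower and 7 did not pass, with a median of -0.23 and a mean of 0.22 (adjusted p = 0.886 with an estimated correlation). Markers of macrophages were higher in Gough for 14 of 20 members and lower for none. When adjusted over the list alone 17 passed, and the median log2 difference was 0.71. Examples were Cd163, a haemoglobin scavenger receptor (2.88 ± 0.19), and the lysosomal protease gene Ctss (0.76 ± 0.08). Lymphocyte markers were higher for 8 of 9 members, with Lck (-0.52 ± 0.07) as the exception and 9 passing when adjusted over the list alone. Of 18 other haematopoietic genes 10 were higher and 2 lower, among them Kit (-0.65 ± 0.06), the stem cell factor receptor. With the preset correlation of camera, adjusted p was 1.4e-05 for the macrophage list and 0.033 for both other lists, but adjusted p = 0.815 with an estimated correlation for each of the 3.

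Of 20 genes of fatty acid and triglyceride synthesis in the E16.5 liver, 13 were lower in Gough, 2 were higher and 5 did not pass, and 15 passed when adjusted over the list alone. Gpam, the first enzyme of glycerolipid synthesis, differed by -0.84 ± 0.13 and the desaturase gene Fads2 by -0.85 ± 0.13. Of 25 genes of fatty acid oxidation and ketogenesis, 14 were higher, 3 were lower and 8 did not pass, with Plin2, a lipid droplet coat gene, at 0.87 ± 0.07. On the TPM scale (limma-trend on log2(TPM + 1), without TMM) that split was 7 higher and 5 lower. With the effective-length offset it was 13 higher and 3 lower. The TPM setting changes the test and the library scaling as well as the length scaling. Matrix and stellate cell genes were lower for 15 of 22 members and higher for 3 (Mmp2 -0.85 ± 0.09; Reln -0.41 ± 0.06), with 19 passing when adjusted over the list alone. Each of these 3 lists passed camera with the preset correlation (adjusted p = 0.033) and not otherwise (adjusted p = 0.815 with an estimated correlation). Of 28 proliferation genes 13 were lower, including Tyms (-0.58 ± 0.05) and Foxm1 (-0.67 ± 0.09), and 3 were higher. Xenobiotic genes were higher for 16 of 29 members, led by the glutathione transferase gene Gsta3 (1.91 ± 0.15), and lower for 6. Among single genes, Nxpe2 (chromosome 9, 48318006 to 48353454) stood at 337 ± 45.7 CPM in Gough and 1.44 ± 0.22 CPM in WSB. Azgp1 (chromosome 5, 137981520 to 137990233), which encodes a secreted zinc-binding glycoprotein, stood at 46.1 ± 21.4 and 0.36 ± 0.18 CPM, and the lincRNA Redrum (chromosome 18, 54422295 to 54453294) at 69.4 ± 10.4 CPM in Gough and at most 0.0253 CPM in any WSB library. The X-linked Hdx was lower in Gough, at 0.45 ± 0.21 against 15.9 ± 2.62 CPM. A level near 0 in 1 strain can also arise where the reads of that strain do not align to the reference, which was not tested here.

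Across the E16.5 liver, 7718 of 14613 tested genes differed between the strains (3793 higher and 3925 lower in Gough; 52.8%). Of these, 1088 differed by at least 2-fold. On the TPM scale 7381 genes passed, but 2264 were higher and 5117 lower. The balance of directions thus depended on this setting, in which the test and the library scaling also differ. Oxidative phosphorylation genes were higher for 20 of 32 members and lower for none (Cox5a 0.58 ± 0.06; for the list adjusted p = 0.00314 with the preset and adjusted p = 0.815 with an estimated correlation). Likewise, 14 of 36 ribosomal protein genes were higher and 1 lower (adjusted p = 0.0206 with the preset and adjusted p = 0.815 with an estimated correlation). Short genes as a class stood higher in Gough here (median log2 0.14 in the shortest of 5 length classes against -0.13 in the longest), a trend that cannot be separated from sequencing batch, which is not given in the sources used here. With an offset for GC content and length those splits became 12 higher and 8 lower for oxidative phosphorylation and 4 higher and 3 lower for ribosomal proteins.

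In the liver at 2 weeks Cyp4a14, a fatty acid omega-hydroxylase, stood at 316 ± 197 CPM in Gough against 60.6 ± 35.5 in WSB (2.45 ± 0.34, adjusted p = 1.61e-05). The acyl-CoA thioesterase gene Acot1 was higher by 0.99 ± 0.15 (22.7% of its sequence shared with another gene). Of 26 genes of fatty acid oxidation and ketogenesis 16 were higher, none were lower and 10 did not pass. When adjusted over the list alone 17 passed, and the median was 0.32 (adjusted p = 0.000387 with the preset and adjusted p = 0.81 with an estimated correlation). Interferon-stimulated genes were lower for 19 of 27 members and higher for 1, with 23 passing when adjusted over the list alone. Ifi44 differed by -1.94 ± 0.24. The median of the list was -0.61, and camera gave the list adjusted p = 3.5e-07 with the preset and adjusted p = 0.81 with an estimated correlation. Matrix and stellate cell genes were lower for 16 of 22 members and higher for none, including the proteoglycan gene Lum (-1.08 ± 0.12) and Sparc (-0.60 ± 0.10). Camera gave this list adjusted p = 7.97e-06 with the preset and adjusted p = 0.81 with an estimated correlation.

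In the liver at 2 weeks Hamp, which encodes the iron hormone hepcidin, stood at 1.14 ± 1.04 CPM in Gough and 148 ± 44.9 in WSB, and its paralogue Hamp2 at 0.17 ± 0.14 and 229 ± 70.5. Since 33.7% and 23.1% of their sequences were shared, reads could have moved between them, but both were low in Gough. Tfrc, the transferrin receptor gene, was higher in Gough (0.89 ± 0.10). The phenobarbital-inducible Cyp2b10 was lower (1.52 ± 0.52 against 30.5 ± 6.41 CPM). Of 31 xenobiotic genes 10 were lower, 1 was higher and 20 did not pass (adjusted p = 0.0466 with the preset and adjusted p = 0.81 with an estimated correlation). Upp2 (chromosome 2, 58567298 to 58792971), a uridine phosphorylase gene, stood at 0.55 ± 0.17 and 264 ± 126 CPM. Of 19 genes of bile acid synthesis and transport 10 were lower and 1 was higher, with 12 passing when adjusted over the list alone (Hsd3b7 -0.71 ± 0.09; Amacr 0.33 ± 0.07; for the list adjusted p = 0.0154 with the preset and adjusted p = 0.81 with an estimated correlation). Cyp7a1, the rate-limiting enzyme gene, did not pass (-0.40 ± 0.26, adjusted p = 0.244). Igfbp3 was again higher (126 ± 17.0 against 59.7 ± 11.8 CPM; 1.08 ± 0.11, adjusted p = 9.82e-08). Igfals, which encodes its partner in the circulating complex, was lower (-0.90 ± 0.27, adjusted p = 0.0134). Igf1 did not pass at this age (-0.40 ± 0.18, adjusted p = 0.0979), nor did Igf2 (0.27 ± 0.56, adjusted p = 0.743), Ghr (-0.17 ± 0.13, adjusted p = 0.323) or Fasn (-0.47 ± 0.25, adjusted p = 0.15). Scd1, a stearoyl-CoA desaturase gene, was higher (68.5 ± 62.9 against 21.8 ± 4.25 CPM, adjusted p = 0.00672), with 1 Gough male at 220 CPM. The test called 5086 of 14278 genes (2701 higher, 2385 lower; 35.6%), 1063 of them with at least a 2-fold difference.

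In the liver at 4 weeks Timd4, a marker of resident macrophages, was higher in Gough by 1.94 ± 0.17 (adjusted p = 2.11e-08). In all, 18 of 20 macrophage markers were higher and none lower, and the median was 1.03 (adjusted p = 3.04e-07 with the preset and adjusted p = 0.885 with an estimated correlation). The leukocyte gene Ptprc was higher by 1.41 ± 0.22. Of 28 proliferation genes 17 were higher and 1 was lower, and 21 passed when adjusted over the list alone. For this list camera gave adjusted p = 0.00128 with the preset and adjusted p = 0.885 with an estimated correlation. The replication gene Mcm6 differed by 1.77 ± 0.28. The lower gene was Tyms (-0.53 ± 0.10, adjusted p = 0.000519), whose difference turned to 0.17 with an effective-length offset and 0.14 on the TPM scale, neither of which passed. Oxidative phosphorylation genes were lower for 17 of 32 members and higher for none, with 22 passing when adjusted over the list alone (Uqcrfs1 -0.42 ± 0.08, a complex III subunit; for the list adjusted p = 3.08e-05 with the preset and adjusted p = 0.885 with an estimated correlation). Secreted hepatocyte and urea cycle genes were lower for 10 of 17 members and higher for none, among them the apolipoprotein genes Apoc3 (-0.95 ± 0.17) and Apoa1 (-0.83 ± 0.15). For this list camera gave adjusted p = 0.00101 with the preset and adjusted p = 0.885 with an estimated correlation.

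The metallothionein genes Mt1 (chromosome 8, 94179082 to 94180327; 2.80 ± 1.99 against 70.4 ± 70.1 CPM, adjusted p = 7.34e-05) and Mt2 (2.10 ± 1.92 against 74.0 ± 78.5 CPM, adjusted p = 0.000109), which bind zinc and copper, were lower in Gough at 4 weeks. Upp2 stood at 7.66 ± 23.2 and 300 ± 137 CPM, the Gough mean resting on female replicate 2 (73.8 CPM; mean 0.312 CPM without it). Elovl3, a fatty acid elongase gene, stood at 0.42 ± 1.1 CPM in Gough (0.0755 without the same female) and 98.5 ± 140 CPM in WSB (56.9 without WSB male replicate 5). Igfbp3 remained higher (55.9 ± 12.3 against 16.7 ± 4.39 CPM; 1.74 ± 0.16, adjusted p = 3.03e-08). By contrast Igfbp2, another IGF-binding protein gene, was lower (84.6 ± 37.8 against 237 ± 62.1 CPM; -1.52 ± 0.23, adjusted p = 4.68e-05). Igf1 (0.19 ± 0.14, adjusted p = 0.279), Ghr (0.14 ± 0.08, adjusted p = 0.163) and Socs2 (0.14 ± 0.29, adjusted p = 0.731) did not pass, nor did the metabolic genes Cpt1a (-0.01 ± 0.11, adjusted p = 0.945), Pck1 (-0.50 ± 0.36, adjusted p = 0.289) and Fasn (-0.70 ± 0.32, adjusted p = 0.0906). Of the 20 genes of the growth hormone and IGF list, 4 were higher, 5 lower and 11 did not pass, with 9 passing when adjusted over the list alone. The major urinary protein genes Mup16, Mup11 and Mup13, named by the rule for high increases, stood at 3164, 11250 and 7640 CPM against 1.31, 73.1 and 57.7 CPM, where the 73.1 CPM of Mup11 in WSB became 47.8 CPM without female replicate 5. Because 95.6%, 83.3% and 95.1% of their sequences were shared within the family, the member that carried the reads is uncertain. In total 4896 of 13374 genes passed (2525 higher, 2371 lower; 36.6%), 1153 by at least 2-fold. Genes rich in GC stood lower in Gough as a class (median log2 -0.23 in the highest of 5 GC classes against 0.1 in the lowest). This trend cannot be separated from sequencing batch.

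No list passed camera with an estimated correlation in the liver: 0 of 31 at each age, and 0 at unadjusted p under 0.05. With the preset correlation 9, 10 and 4 lists passed at E16.5, 2 weeks and 4 weeks, and the self-contained fry test called 20, 13 and 5.

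The strain difference in the liver changed with age for several growth genes. The CPM of this paragraph were scaled over the 60 liver libraries together, and so differ from those given for each age alone. In that joint fit the Igf1 difference fell by 0.71 ± 0.21 on the log2 scale from E16.5 to 2 weeks (adjusted p = 0.00841) and rose by 0.61 ± 0.21 from 2 to 4 weeks (adjusted p = 0.0311, and up to 0.0634 without 1 library). The Igfbp3 difference followed the same course (-0.81 ± 0.17, adjusted p = 0.000247, then 0.68 ± 0.17, adjusted p = 0.00325), although Gough stayed above WSB at all 3 ages. Igf2r changed by 0.34 ± 0.12 from E16.5 to 2 weeks (adjusted p = 0.0324, and up to 0.0596 without 1 library) and not afterwards (0.04 ± 0.12, adjusted p = 0.85). The change of Igf2 did not pass in either step (0.75 ± 0.56, adjusted p = 0.365, and -1.52 ± 0.61, adjusted p = 0.0732). The Scd1 difference changed by 2.46 ± 0.63 (adjusted p = 0.003) and then by -2.24 ± 0.63 (adjusted p = 0.00946), but 2 libraries carried much of this. Without Gough male 2-week replicate 5 the Scd1 changes were 1.86 ± 0.58 (adjusted p = 0.014) and -1.64 ± 0.58 (adjusted p = 0.0366). Without WSB female 4-week replicate 5 the second Scd1 change was -1.57 ± 0.57 (adjusted p = 0.038), and without both libraries it did not pass (-0.97 ± 0.50, adjusted p = 0.155). Afp, the fetal serum protein gene, changed by -3.55 ± 0.77 from 2 to 4 weeks (adjusted p = 0.000896). Hamp turned over at both steps, with 15.2, 1.16 and 145 CPM in Gough and 0.82, 151 and 79.5 CPM in WSB at E16.5, 2 weeks and 4 weeks. Azgp1 stood at 35.9 against 0.29 CPM at E16.5, 900 against 948 CPM at 2 weeks and 1355 against 1520 CPM at 4 weeks (adjusted p = 1.49e-24 for the first change). The glutathione transferase gene Gstp3 stood at 140 against 62.2 CPM at E16.5 and 836 against 21.3 CPM at 2 weeks. Prrg1, a membrane protein gene of the vitamin K-dependent Gla family, was alike at E16.5 (5.49 against 6.26 CPM) and reached 35.6 against 5.92 CPM at 2 weeks and 64.5 against 2.04 CPM at 4 weeks. Of 15136 genes, the strain difference changed for 3492 between E16.5 and 2 weeks (1900 up, 1592 down) and for 2848 between 2 and 4 weeks (1728 up, 1120 down). On the TPM scale the first count was 4609, split 3518 up and 1091 down, with the median of all genes at 0.12.

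**Figure D1:**
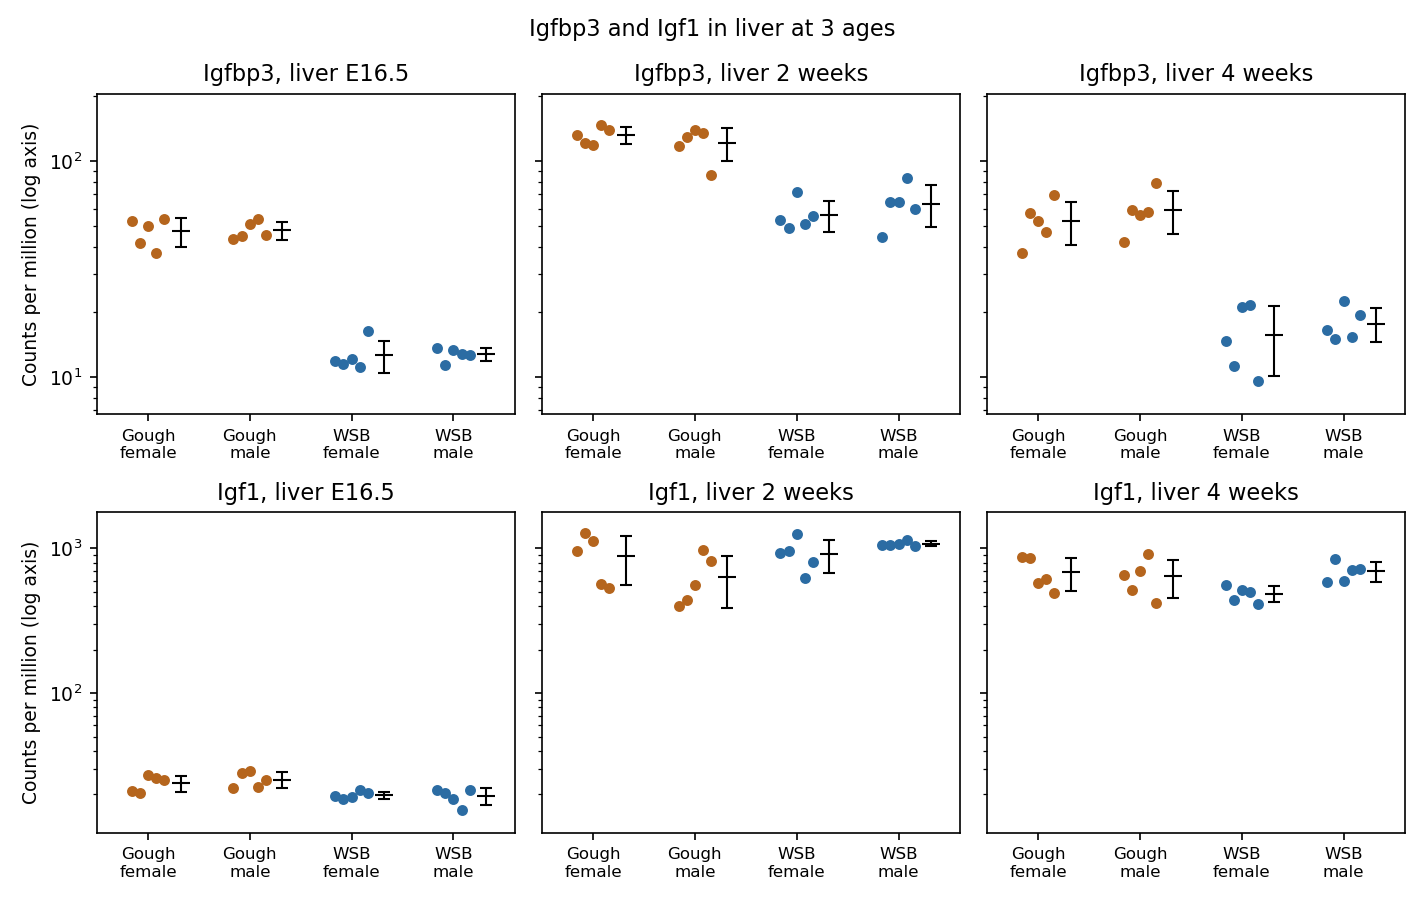
Igfbp3 and Igf1 in the liver at E16.5, 2 weeks and 4 weeks, in CPM on a log axis; each point is 1 animal and the bars give mean ± SD of each strain-by-sex group (n = 5). Igfbp3 lay higher in Gough at all 3 ages (47.4 against 12.7, 126 against 59.7 and 55.9 against 16.7 CPM), while the Igf1 values of the strains overlapped at every age.

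In the hypothalamus Opalin, an oligodendrocyte membrane protein gene, was higher in Gough by 0.74 ± 0.09 (adjusted p = 4.81e-06) and Mobp, a myelin structural gene, by 0.52 ± 0.10 (adjusted p = 0.00072). Of 17 oligodendrocyte and myelin genes 13 were higher and none lower, and 14 passed when adjusted over the list alone. The median was 0.44 (adjusted p = 2.9e-06 with the preset and adjusted p = 0.333 with an estimated correlation). Microglia markers were higher for 11 of 15 members and lower for none, with 12 passing when adjusted over the list alone. Fcrls stood at 8.13 ± 1.80 against 2.99 ± 0.48 CPM (1.44 ± 0.13, adjusted p = 2.98e-08), and the list had adjusted p = 3.59e-07 with the preset and adjusted p = 0.192 with an estimated correlation. Macrophage markers were higher for 8 of 14 members, led by Csf1r (0.50 ± 0.06) and Adgre1 (0.89 ± 0.11), and the list had adjusted p = 6.12e-05 with the preset and adjusted p = 0.192 with an estimated correlation. The complement gene C4b was higher by 1.65 ± 0.13. Astrocyte markers were higher for 6 of 14 members, such as Aldh1l1 (0.66 ± 0.09), whereas 17 of 18 neuronal markers did not pass. Some markers of neighbouring regions also passed, with 4 of 11 striatum markers lower and none higher and 2 of 11 thalamus markers higher and none lower, where 22.3% of all tested genes passed. The dissected region was not shown to be the same in both strains.

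Among the feeding peptides and receptors of the hypothalamus, Mc4r (chromosome 18, 66857704 to 66860506), the melanocortin receptor that restrains feeding, was lower in Gough at 3.19 ± 0.65 against 4.43 ± 0.66 CPM (-0.48 ± 0.10, adjusted p = 0.00171). Nucb2, the precursor of nesfatin, was lower by -0.27 ± 0.05 (adjusted p = 0.000613) and Pmch, which encodes melanin-concentrating hormone, by -0.28 ± 0.08 (adjusted p = 0.0181; 52.4% of its sequence shared). The list had 1 higher and 4 lower of 26 members, with 5 passing when adjusted over the list alone (adjusted p = 0.626 with an estimated correlation). Values that did not pass were -0.13 ± 0.23 for Agrp (adjusted p = 0.753), -0.23 ± 0.18 for Npy (adjusted p = 0.429) and 0.37 ± 0.27 for Pomc (adjusted p = 0.364). The same held for Cartpt (-0.25 ± 0.11, adjusted p = 0.114) and the leptin receptor gene Lepr (-0.13 ± 0.21, adjusted p = 0.729). Of 23 releasing hormone and neuroendocrine genes 1 was higher (Pgr, the progesterone receptor gene, 0.42 ± 0.07) and 1 lower (Crhbp -0.46 ± 0.11). Ghrh, the growth hormone-releasing hormone gene, differed by -0.45 ± 0.17 (adjusted p = 0.0662) and passed at -0.51 with the GC and length offset (adjusted p = 0.00297). Sst (0.07 ± 0.16, adjusted p = 0.817) and Trh (0.15 ± 0.16, adjusted p = 0.568) did not pass. None of 18 growth hormone and IGF genes and none of 19 hypothalamic transcription factor genes passed in edgeR, while with the GC and length offset 2 and 1 were lower. That offset gave 1 higher and 7 lower feeding genes.

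In the hypothalamus, of 21 genes of fatty acid and triglyceride synthesis 10 were higher in Gough and none lower, 13 passed when adjusted over the list alone, and Scd1 differed by 0.60 ± 0.06 (adjusted p = 1.02e-07). Camera gave adjusted p = 0.000141 with the preset and adjusted p = 0.192 with an estimated correlation, and the split was 12 higher and none lower with the GC and length offset. All 11 mitochondrially encoded genes that passed, of 13, were lower, among them mt-Nd4 (-0.62 ± 0.09) and mt-Nd4l (-0.67 ± 0.10), and the list had adjusted p = 7.04e-08 with the preset and adjusted p = 0.417 with an estimated correlation. Of 32 nuclear oxidative phosphorylation genes none passed in edgeR, but 12 were higher and none lower on the TPM scale, and 5 were higher and 1 lower with the GC and length offset. Cryab, a small heat shock protein gene, stood at 54.5 ± 8.01 against 3.82 ± 1.29 CPM. Thalamus markers were high in Gough male replicates 1 and 4, whose scores (mean log2 level of the markers, centred over the libraries) were 1.78 and 0.87 against at most 0.19 in the others. Of these markers Plekhg1 (1.18 ± 0.17) and Prkcd (1.27 ± 0.31) passed, but the Gough mean of Prkcd fell from 29.9 to 19.4 CPM without Gough male replicate 1 (124 CPM). Plekhg1 was also higher in the E16.5, 2-week and 4-week liver and in fat (1.00, 0.73, 1.00 and 0.78), so its difference is not particular to this region. Altogether 3567 of 16001 genes passed (1872 higher, 1695 lower; 22.3%), 544 by at least 2-fold, and 3334 passed without these 2 libraries. Genes rich in GC stood higher in Gough as a class (median log2 0.11 in the highest of 5 GC classes against -0.03 in the lowest). This trend cannot be separated from sequencing batch. On the TPM scale 4223 passed, 3125 higher and 1098 lower. With an estimated correlation 0 of 34 lists passed camera (3 at unadjusted p under 0.05), against 5 with the preset and 13 in fry.

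In gonadal fat at 4 weeks, Gough mice had more leptin mRNA. The Gough fat came from the animals of the liver and hypothalamus, but the WSB fat came from other WSB animals. Any difference in how that set was kept or sampled cannot be told apart from strain in fat. Lep (chromosome 6, 29060220 to 29073877), which encodes leptin, the hormone that reports fat stores, stood at 980 ± 567 CPM in Gough and 201 ± 162 in WSB (2.30 ± 0.34, adjusted p = 1.56e-05). The strains did not overlap in either sex. Mest (chromosome 6, 30723547 to 30748465), an imprinted gene that rises with fat cell growth, stood at 639 ± 534 against 51.7 ± 27.6 CPM (3.49 ± 0.36, adjusted p = 1.76e-07). Of its sequence 22% was shared, and it overlaps Copg2 on the opposite strand, which the counts cannot separate. Of 8 fat expansion genes 5 were higher and none lower, including Bmp3 (1.80 ± 0.19), and the list had adjusted p = 0.0242 with the preset and adjusted p = 0.711 with an estimated correlation. Pdk4, a kinase gene that shifts fuel use from glucose to fat, was lower at 56.0 ± 23.4 against 635 ± 228 CPM (-3.48 ± 0.27, adjusted p = 2.64e-09). Irs2, an insulin receptor substrate gene, was lower at 2.70 ± 0.78 against 15.0 ± 5.74 CPM (-2.47 ± 0.21, adjusted p = 8.13e-09). Of 24 genes of fatty acid oxidation 18 were lower and 3 higher, with 21 passing when adjusted over the list alone. Camera gave this list adjusted p = 6.64e-05 with the preset and adjusted p = 0.386 with an estimated correlation. Its member Acadl differed by -1.21 ± 0.09.

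Thermogenic genes of fat were lower for 12 of 16 members and higher for 2, with 14 passing when adjusted over the list alone. The transcription factor genes Ppara (-2.45 ± 0.31) and Prdm16 (-1.02 ± 0.13) were examples, and the list had adjusted p = 0.00807 with the preset and adjusted p = 0.637 with an estimated correlation. Fatty acid and triglyceride synthesis genes were lower for 9 of 21 members and higher for none (Fasn -1.04 ± 0.26, adjusted p = 0.0023; Acacb -1.42 ± 0.23), and the list had adjusted p = 0.0475 with the preset and adjusted p = 0.786 with an estimated correlation. Adipocyte identity genes were lower for 10 of 22 members and higher for 2 (Aqp7, the glycerol channel gene, -1.03 ± 0.09; for the list adjusted p = 0.0242 with the preset and adjusted p = 0.637 with an estimated correlation). Adipoq (-0.07 ± 0.10, adjusted p = 0.565) and Pparg (-0.14 ± 0.12, adjusted p = 0.314) did not pass. Lipolysis genes were lower for 7 of 16 members and higher for 2, including Pnpla2, the first triglyceride lipase gene (-0.56 ± 0.07). Cholesterol synthesis genes went the other way, with 16 of 25 higher, 1 lower and 18 passing when adjusted over the list alone. For these genes camera gave adjusted p = 0.00378 with the preset and adjusted p = 0.786 with an estimated correlation. Of the growth hormone and IGF genes 8 of 19 were lower and 2 higher, with 10 passing when adjusted over the list alone and Igfbp5 at -1.08 ± 0.12. Mitochondrially encoded genes were lower for 12 of 13 members (adjusted p = 0.000129 with the preset and adjusted p = 0.711 with an estimated correlation). Of 32 nuclear oxidative phosphorylation genes 9 were higher and 8 lower, a split that was 15 to 4 on the TPM scale and 4 to 15 with the GC and length offset.

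**Figure D2:**
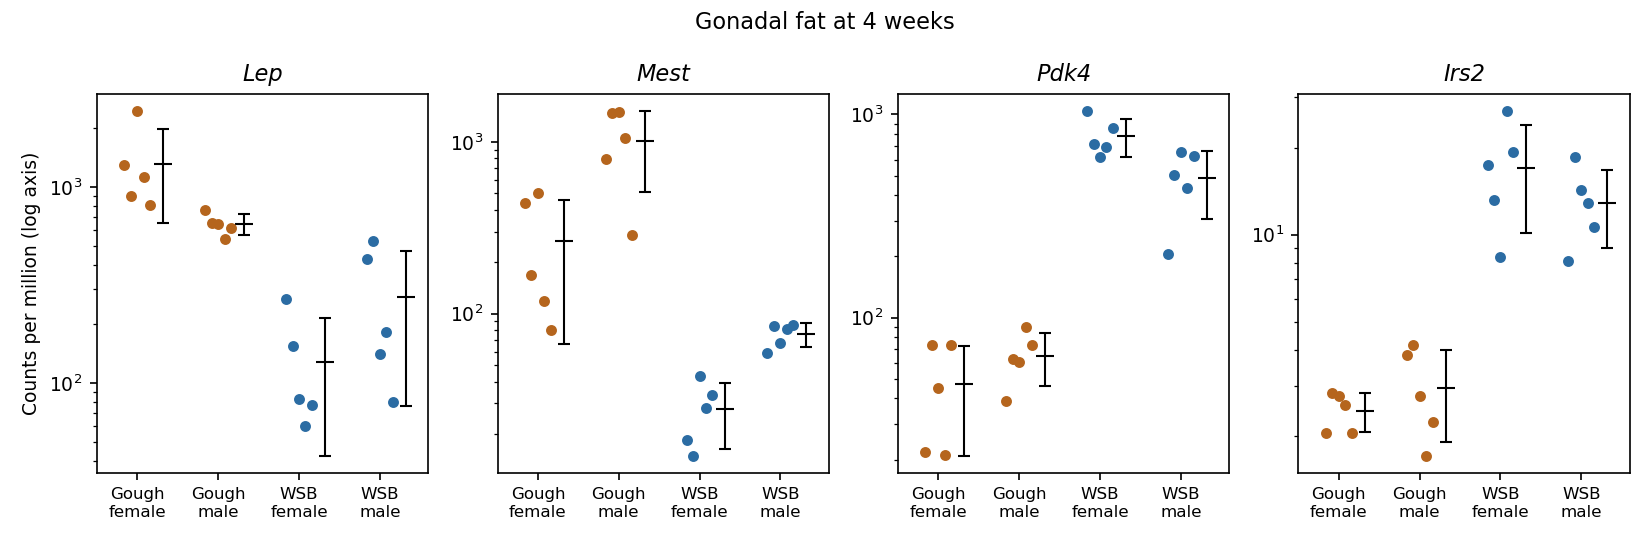
Lep, Mest, Pdk4 and Irs2 in gonadal fat at 4 weeks, in CPM on a log axis; each point is 1 animal and the bars give mean ± SD of each strain-by-sex group (n = 5). Lep and Mest lay higher in Gough (980 against 201 and 639 against 51.7 CPM over both sexes) and Pdk4 and Irs2 lower (56.0 against 635 and 2.70 against 15.0 CPM).

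Acute phase and complement genes of fat were higher for 8 of 15 members and lower for 4 (adjusted p = 0.37 with the preset and adjusted p = 0.786 with an estimated correlation). Among the higher were C4b (488 ± 260 against 47.5 ± 26.9 CPM) and Lcn2, an iron-binding innate immune protein gene (19.9 ± 15.0 against 2.33 ± 0.98 CPM). Macrophage markers did not share a direction (4 higher, 6 lower, 9 not passing; median -0.05, mean 0.03, a median of 0.06 on the TPM scale, and -0.31 with 3 higher and 9 lower with the GC and length offset). Lymphocyte markers were higher for 9 of 17 members and lower for 1. Reproductive tract markers were higher for 6 of 8 members and lower for none. Levels were low for some, as in Gdf9, an oocyte gene (0.61 ± 0.33 against 0.12 ± 0.08 CPM). The list also holds the epithelial genes Krt8, Krt18 and Epcam, and Krt8 ranged from 4.11 CPM in Gough male replicate 1 to 42.2 CPM in replicate 4. Epcam, an epithelial gene chosen after its values were seen, stood at 26.1, 17.7 and 17.5 CPM in Gough male replicates 4, 2 and 5, at 4.10 CPM in Gough female replicate 5 and 3.79 CPM in WSB female replicate 2, and at no more than 0.72 CPM in the other 15 libraries. In total 8095 of 14980 genes passed (4354 higher, 3741 lower; 54%), 1474 by at least 2-fold, and 6310 passed without those 5 libraries (3230 higher, 3080 lower). Short genes as a class stood higher in Gough fat (median log2 0.17 in the shortest of 5 length classes against -0.12 in the longest). As at E16.5, this trend cannot be separated from sequencing batch. With the GC and length offset 1196 of the calls were lost. On the TPM scale 8439 passed, 6146 higher and 2293 lower, with the median of all genes at 0.13. Of 31 lists 0 passed camera with an estimated correlation (2 at unadjusted p under 0.05), against 8 with the preset and 17 in fry.

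Part of the strain difference was shared by all 5 conditions. Of 12267 genes tested in each, 399 passed in the same direction throughout (215 higher and 184 lower in Gough), against 5.6 expected for independent lists; 88 passed in all 5 with mixed directions, and 1525 passed in none. Examples, named after their values were seen, were the ribosomal protein gene Rpl12 (1.97, 1.94, 1.97, 1.63 and 1.98 in the order E16.5, 2-week and 4-week liver, hypothalamus and fat), the crystallin gene Cryab (3.48, 2.50, 1.75, 3.82 and 4.52) and the aldehyde oxidase gene Aox1 (-2.24, -1.77, -2.05, -2.18 and -2.91). H2-Eb1, a class II antigen presentation gene, was higher in Gough in every condition and stood at 35.0 ± 13.4 against 0.91 ± 0.25 CPM in fat. The 2-week and 4-week livers were the most alike pair, with 94.2% of the genes called in both going the same way (1166 both higher against 466 expected and 1167 both lower against 402.2 expected), and the 4-week liver and fat had the lowest share at 70.2%. Across all genes tested in both, the log2 differences correlated least between the 4-week liver and the hypothalamus (r 0.56). Liver and hypothalamus at 4 weeks came from the same animals, and the Gough fat from these Gough animals too, which the expected 5.6 ignores. Of the 399 genes, 122 shared at least 20% of their sequence with another gene. Reads of a strain that do not align to the reference could also shift a gene alike in every condition, which was not tested.

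**Figure D3:**
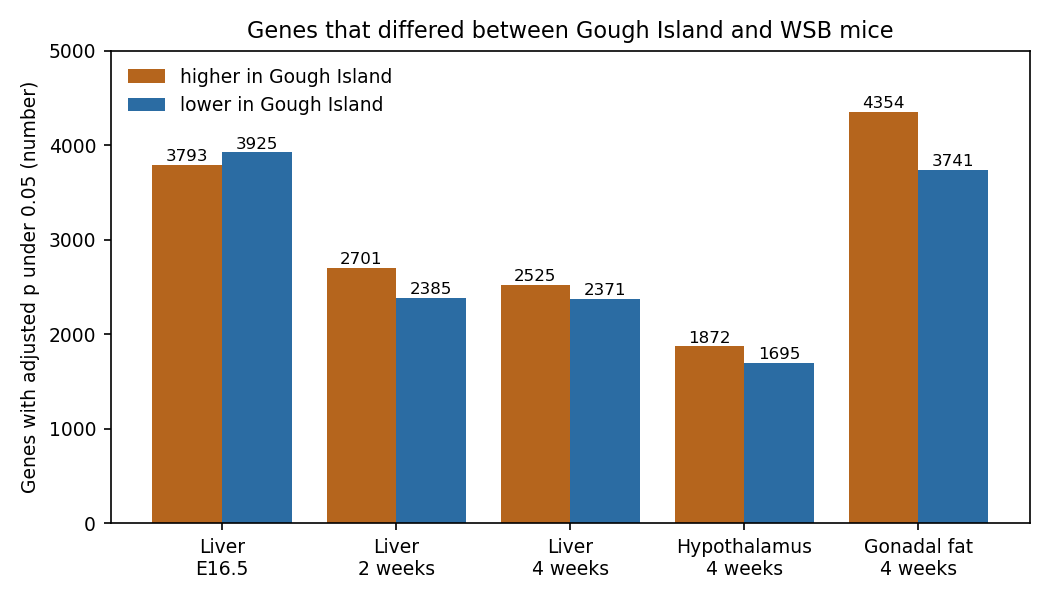
Number of genes higher and lower in Gough Island than in WSB mice in each condition (bars, y axis: genes with adjusted p under 0.05, starting at 0). The counts were 3793 and 3925 in the E16.5 liver, 2701 and 2385 at 2 weeks, 2525 and 2371 at 4 weeks, 1872 and 1695 in the hypothalamus, and 4354 and 3741 in gonadal fat.

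**Figure D4:**
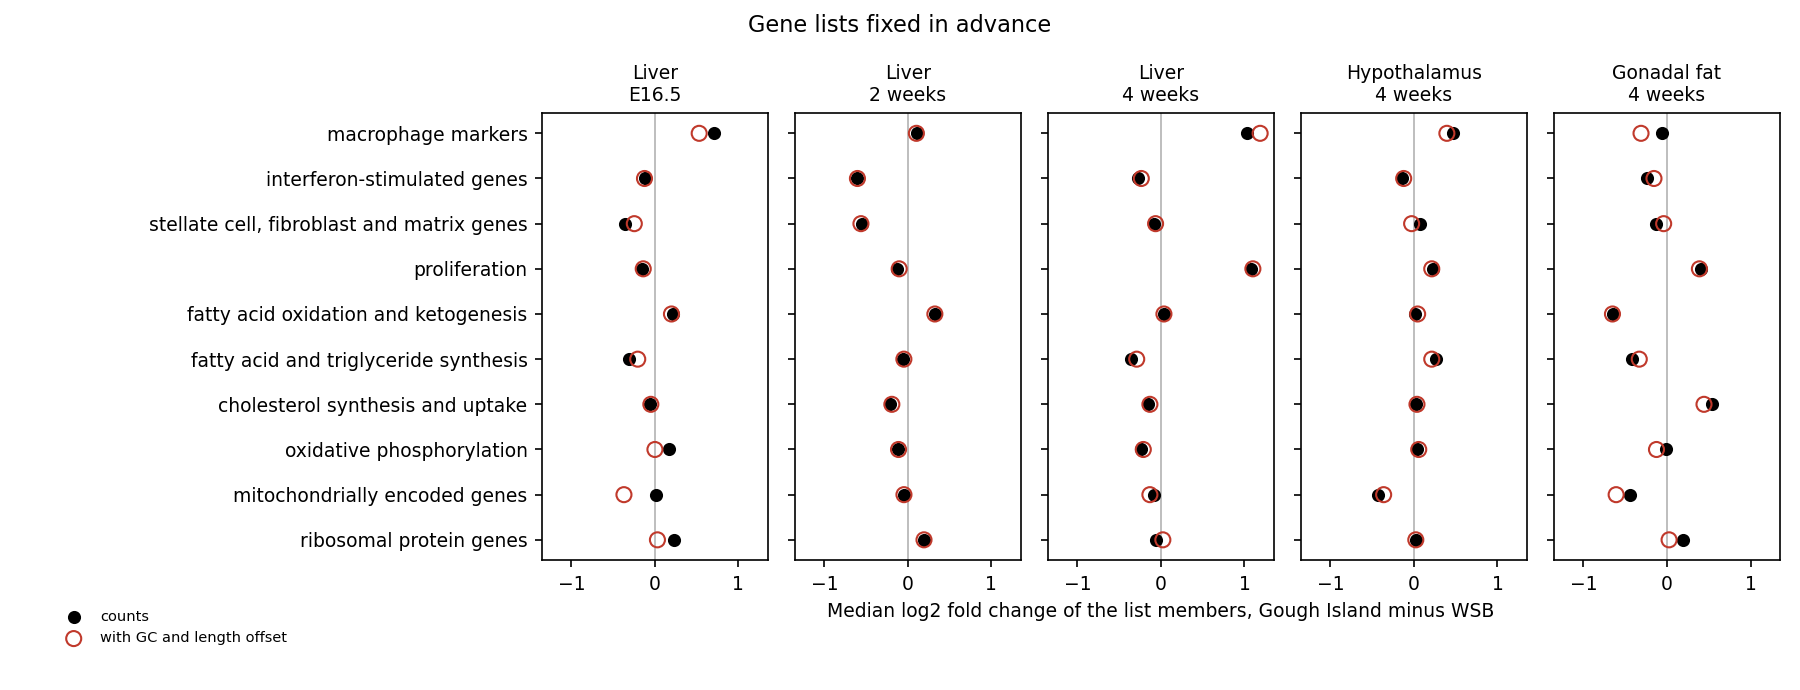
Median log2 difference (x axis, Gough minus WSB) of the members of 10 gene lists in each condition, from counts (filled) and with the GC and length offset (open). Macrophage markers lay at 1.03 in the 4-week liver and fatty acid oxidation genes at -0.65 in fat by counts. Medians near 0 turned, as for ribosomal protein genes in the 4-week liver (-0.05 by counts, 0.02 with the offset) and mitochondrially encoded genes at E16.5 (0.01 and -0.37). On the TPM scale, which is not drawn, the fat medians were 0.06 for macrophage markers (-0.05 by counts) and 0.16 for oxidative phosphorylation genes (-0.01 by counts).

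Sex chromosome genes matched the labelled sex in every group. Xist, the X inactivation RNA, averaged 1180 and 1174 CPM in Gough and WSB female livers at E16.5 against 1.60 and 0.57 CPM in males. The Y-linked Ddx3y averaged 96.9 and 91.8 CPM in males against 0.009 and 0.03 CPM in females. In edgeR the sex difference, sex chromosome genes included, called 80 genes at E16.5 (44 higher and 36 lower in males), 12 in the liver at 2 weeks (6 and 6), 199 at 4 weeks (59 and 140) and 20 in the hypothalamus (8 and 12). DESeq2 called 910, 20, 479 and 40 in the same order, voom with quality weights 1476 in the 4-week liver, and 3568 genes at E16.5 had an unadjusted p under 0.05 in edgeR, so the counts of the liver depend on the method. In fat edgeR called 3611 of 14980 genes (1791 higher and 1820 lower in males). Among them were the positional genes Hoxa9 (26.7 and 28.9 CPM in females, 1.72 and 0.39 CPM in males) and Hoxa10 (29.5 and 21.6 CPM in females, 0.10 and 0.03 CPM in males). The gonadal depot may thus differ in position between the sexes, which cannot be told apart from sex in fat. Without the 5 libraries high in Epcam 2002 passed. Single libraries carried some of these counts: the E16.5 count was 15 without WSB female replicate 2 and 1268 without Gough male replicate 1. The 4-week liver count was 97 without WSB female replicate 2 and 434 without Gough female replicate 1. The E16.5 count was 43, split 13 to 30, with the GC and length offset, and the 4-week liver count was 153, split 87 to 66, on the TPM scale.

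The strain difference depended on sex mainly in fat, where sex cannot be told apart from the position of the gonadal depot. There 969 genes had a different strain effect in males and females (475 more positive and 494 more negative in males). Irf8, a myeloid transcription factor gene, stood at 18.0 ± 1.56 CPM in Gough females and 5.10 ± 1.01, 4.71 ± 1.07 and 5.26 ± 0.69 CPM in Gough males, WSB females and WSB males (n = 5 each; edgeR adjusted p = 4.36e-05). C6, a complement gene, stood at 10.3, 2.12, 3.46 and 10.7 CPM in the same order. Ucp1, the uncoupling protein gene of thermogenic fat, stood at 27.2 ± 27.9, 23.7 ± 27.0, 234 ± 104 and 4.21 ± 4.65 CPM in the same order (interaction 5.58 ± 1.14, edgeR adjusted p = 0.00764). Single libraries carried part of these Ucp1 means: without replicate 1 the Gough female mean was 15.3 CPM, without replicate 4 the Gough male mean was 11.8 CPM, and without replicate 2 the WSB male mean was 2.35 CPM. The Ucp1 interaction was 4.58 ± 1.02 (adjusted p = 0.0168) without Gough male replicate 4, and did not pass without the 5 libraries high in Epcam, of which this is 1 (4.25 ± 1.17, adjusted p = 0.0949). Lpl, the lipoprotein lipase gene, stood at 10970, 8971, 10790 and 15000 CPM (-0.77 ± 0.19, adjusted p = 0.0223), and without those 5 libraries its interaction was no smaller but its SE was wider (-0.80 ± 0.22, adjusted p = 0.0842). The Lep difference was 3.36 in females and 1.24 in males, and its interaction did not pass (-2.11 ± 0.65, adjusted p = 0.0579). Without the 5 libraries high in Epcam the interaction count was 217 (93 and 124), and on the TPM scale it was 922 (285 and 637). Other settings gave more, with 1525 in DESeq2 and 1528 with the GC and length offset.

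Elsewhere few genes showed a strain-by-sex interaction in the edgeR fit of each condition alone. In the 4-week liver DESeq2 called 134 and the fit of all 100 libraries 314, so that count depends on the method. In the liver at 4 weeks 23 genes passed (8 and 15), led by Cldn34c1, a claudin family gene on the X chromosome (123103495 to 123188795), with 5.79 ± 0.63 CPM in Gough males and 0.90 to 1.47 CPM in the other groups (edgeR adjusted p = 0.00731). The sodium channel subunit gene Scn4b had 4.67 CPM in Gough males and 0.15 to 0.41 CPM elsewhere. Cldn34c1 was also the single gene at 2 weeks (5.73 CPM in Gough males against 1.11 to 1.48 CPM, adjusted p = 0.00308). In the hypothalamus 6 passed in edgeR (0 and 6), with the detoxifying glyoxalase gene Glo1 at 221 ± 32.6 CPM in Gough females and 112 to 118 CPM in the other groups (edgeR adjusted p = 0.000116). The cilium gene Rsph1 stood at 60.4 CPM against 11.3 to 14.0 CPM. At E16.5 the single gene was Xist (1.63 ± 0.24, adjusted p = 0.0151), from male levels of 1.60 and 0.57 CPM in Gough and WSB, and the sign turned on the TPM scale (-0.17). No gene passed at E16.5 with the embryo block or with the effective-length offset. On the TPM scale the 4-week liver had 28 genes (17 and 11) and the hypothalamus 7 (2 and 5), and with the GC and length offset the hypothalamus had 8 (1 and 7). The 4-week liver count was 11 without Gough male replicate 3 and 62 without WSB female replicate 5. The 2-week count was 5 without Gough male replicate 4, and the E16.5 count was 0 (edgeR) without Gough male replicate 3 and 7 without Gough male replicate 4.

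A gene outside the naming rule, chosen after its values were seen, divided the Gough animals in both organs. Tpm3-rs7 (chromosome 14, 113314608 to 113316754), a Tpm3-related sequence, lay between -0.14 and 0.53 log2 CPM in the 4-week liver of 5 Gough animals and between 4.65 and 5.04 in the other 5, while all 10 WSB animals lay between 5.28 and 5.81. The same 5 Gough animals were low in the hypothalamus (-0.28 to 1.59, against 5.35 to 5.61 in the others), and both divisions held animals of both sexes. Since 78.6% of its sequence was shared with other genes, Tpm3 being the closest, reads of the parent gene could have been assigned to it. Tpm3 also followed the Gough animals between the organs (within-sex r 0.978). Its within-sex SD in liver was 0.51 log2 CPM in Gough and 0.19 in WSB, so reads may have moved between these genes.

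**Figure D5:**
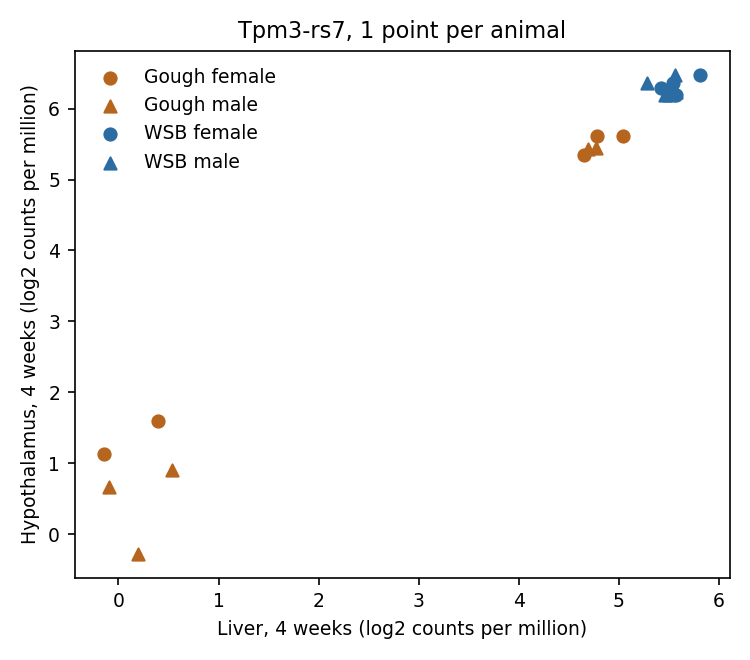
Tpm3-rs7 level in the liver (x axis) and hypothalamus (y axis) at 4 weeks, in log2 CPM, with 1 point per animal marked by strain and sex. The low Gough animals lay at -0.14 to 0.53 in liver and -0.28 to 1.59 in hypothalamus, apart from the other Gough animals and from WSB.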

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

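The values in this part were picked out by rules set before the data were examined: 1 library of a group far from the other 4, or a strain difference that changed with sex or age. The distance rule was passed by 19 of 220 groups of values; chance alone flags about 1 in 20, or 11 here, so some of these will be chance.

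Library totals stood apart for Gough female 4-week liver replicate 2 (46.6 M, in mega counts, against 19.1 to 27 in the others), Gough male 4-week liver replicate 2 (84.6 against 19.9 to 25.8), WSB male 4-week liver replicate 4 (29.8 against 17.1 to 20.5), Gough male hypothalamus replicate 3 (58.9 against 16.6 to 19.7) and WSB female fat replicate 2 (28.6 against 24.9 to 25.9). In the liver, Afp at E16.5 was 3.23e+04 CPM in WSB female replicate 5 against 3.5e+04 to 3.58e+04, and Scd1 at 2 weeks was 220 CPM in Gough male replicate 5 against 13.1 to 65. At 4 weeks the lipid synthesis genes Fasn (1.5e+03 CPM against 475 to 750) and Scd1 (2.01e+04 against 1.52e+03 to 2.79e+03) were both high in WSB female replicate 5, and Igfbp1 was low in WSB male replicate 4 (33.2 against 110 to 134).

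In the hypothalamus, Agrp was 4.69 CPM in Gough male replicate 4 against 7.71 to 8.5, Hcrt was 101 CPM in WSB female replicate 1 against 31.5 to 51.1, and Pmch was 597 CPM in Gough female replicate 2 against 713 to 739. In fat, Pparg was 287 CPM in Gough male replicate 1 against 192 to 214, and Ucp1 was 71.3 CPM in Gough male replicate 4 against 7.28 to 19.6. Fasn was 1.27e+04 CPM in Gough female replicate 2 against 4.16e+03 to 6.04e+03. Adrb3, the beta-3 adrenergic receptor gene, was 143 CPM in Gough female replicate 1 against 184 to 200 and 383 CPM in Gough male replicate 2 against 234 to 275. Cfd, which encodes adipsin, was 5.34e+03 CPM in WSB female replicate 4 against 3.35e+03 to 3.74e+03.

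The strain difference changed with sex for 1, 1, 23, 6 and 969 genes in the liver at E16.5, 2 weeks and 4 weeks, the hypothalamus and fat, and with age in the liver for 3492 and 2848 genes. Among the key genes the change with sex was 5.58 for Ucp1 and -0.77 for Lpl in fat. The change with age was -0.71 and then 0.61 for Igf1, 0.34 for Igf2r in the first step, -3.55 for Afp in the second, and 2.46 and then -2.24 for Scd1.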

How the results depend on the processing

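Of 444 results of named genes for strain, sex, interaction and age, 244 kept their call under every other setting (35 of 91 in the hypothalamus) and 422 with any 1 library left out. Of their 5611 values under other settings, 5322 kept the call, 271 were weaker, 15 were stronger and 3 reversed, and of 9280 values with 1 library left out 9178 kept it, 90 were weaker, 12 were stronger and 0 reversed. The other settings include adjusted p under 0.01 and at least a 2-fold difference. A called gene that misses these stricter limits counts as weaker by definition, so not every lost call is a dependence on processing. The reversed values were Tyms in the 4-week liver with the effective-length offset (0.165) and on the TPM scale (0.136), and the Xist interaction at E16.5 on the TPM scale (-0.172); the cause was not tested. With 1 library left out the strain counts ran from 7298 to 7803 at E16.5, 4651 to 5400 at 2 weeks, 4396 to 5644 in the 4-week liver, 3150 to 3794 in the hypothalamus and 7721 to 8434 in fat, and the count shared by all conditions from 379 to 404. The age counts ran from 3218 to 3720 and from 2284 to 3448. Interaction counts ran from 0 (without Gough male replicate 3) to 7 (without Gough male replicate 4) at E16.5, 1 to 5 at 2 weeks, 11 (without Gough male replicate 3) to 62 (without WSB female replicate 5) in the 4-week liver, 4 (without Gough male replicate 3) to 7 in the hypothalamus, and 670 to 1413 in fat. Sex counts ran from 15 to 1268 at E16.5, 11 to 15 at 2 weeks, 97 to 434 in the 4-week liver, 19 to 24 in the hypothalamus and 3116 to 3820 in fat.

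At adjusted p under 0.01, strain counts were 3302 at 2 weeks, 2951 in the 4-week liver and 2299 in the hypothalamus, interaction counts 0 at E16.5, 4 in the 4-week liver and 257 in fat, sex counts 12 at E16.5, 48 in the 4-week liver and 1891 in fat, age counts 2087 and 1338, and 261 genes were shared by all conditions. With at least a 2-fold difference, strain counts were 1088, 1063, 1153, 544 and 1474 in the order used above, sex counts 7, 7, 60, 12 and 636, the fat interaction count 523, age counts 903 and 688, and 112 genes were shared. DESeq2 gave interaction counts of 34, 8, 134, 17 and 1525 and sex counts of 910, 20, 479 and 40 before fat. Voom with quality weights gave interaction counts of 0, 4, 240, 10 and 1906 and a sex count of 1476 in the 4-week liver. A fit of all 100 libraries gave interaction counts of 9, 15 and 314 in the liver and 1618 in fat, and sex counts of 26, 20, 753 and 37 before fat. At E16.5 the interaction count was 0 with the effective-length offset, on the TPM scale and with the embryo block, 2 without a filter and 2 without the libraries of steepest GC trend. The E16.5 sex count was 37 on the TPM scale, 139 with the embryo block, 125 with upper-quartile scaling, 138 at a mean of 1 CPM, 50 without a filter and 15 without those libraries. Without a filter the 4-week liver sex count was 131. The offset for GC content and length gave sex counts of 43 at E16.5 and 483 in the 4-week liver, interaction counts of 50 in the 4-week liver and 1528 in fat, and 1 list in the hypothalamus. Without the fat libraries high in epithelial markers the interaction count was 217 and the sex count 2002. Lists passing were 9, 10, 4, 5 and 8 in camera with the preset correlation and 20, 13, 5, 13 and 17 in fry. The cause was not tested for the counts that moved, except for those weighed in the last part.

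What could be seen was limited in 3 ways. Interactions of 1.5-fold were recovered in simulation for 6% to 29.9% of genes, so a gene without an interaction call is not shown to be alike in both sexes. That simulation kept the observed depth, spread and group size, so their parts in this limit are not told apart. The WSB embryo libraries were the deepest (median 40.8 M against 21.8 in Gough), and the 4-week livers of Gough held totals from 19.1 to 84.6 M. Genes under the filter were not tested, and their absence from the counts says nothing of their levels.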

Other observations

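Immediate early genes were lower in the Gough liver at 2 weeks for 7 of 15 members and higher for none (Dusp1 -1.39 ± 0.27; Jun -1.60 ± 0.37), and the list had adjusted p = 0.0475 in camera with the preset and adjusted p = 0.81 with an estimated correlation. In fat they were higher for 7 of 17 members and lower for 1 (Fosb 1.03 ± 0.24; Ier2 0.70 ± 0.15). Circadian genes had 4 lower and none higher of 18 in the 2-week liver, including Per1 (-1.12 ± 0.28), and 4 higher and 4 lower of 19 in fat, including Hlf (0.82 ± 0.16) and Tef (-0.42 ± 0.09). Of all tested genes 35.6% passed in the 2-week liver and 54% in fat, so circadian genes did not pass more often than genes at large. Heat shock genes of fat were lower for 6 of 12 members and higher for none (Hsp90ab1 -0.55 ± 0.06), a split of 3 higher and 4 lower on the TPM scale.

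Genes of the endoplasmic reticulum stress list were higher for 7 of 16 members and lower for 2 in the 4-week liver (Pdia4 0.52 ± 0.09; Dnajb9 0.82 ± 0.18), whereas 5 rose and 5 fell of 17 in fat, among them the amino acid response genes Asns (1.70 ± 0.10) and Atf4 (0.58 ± 0.07) on the higher side. Imprinted genes were higher for 3 and lower for 8 of 21 in the E16.5 liver, with Peg10 at -0.60 ± 0.05, and higher for 5 and lower for 4 of 20 in fat, where Mest and Dlk1 (-1.74 ± 0.28), an inhibitor of fat cell maturation, went apart. Of all tested genes 52.8% passed at E16.5 and 54% in fat, so imprinted genes did not pass more often than genes at large. Muscle and pancreas markers in fat had 3 higher and 2 lower of 7, with the muscle actin gene Acta1 at 14.9 against 1.36 CPM.

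The tests weighed below were partly chosen only after the result was seen. This holds for the mitochondrial mRNA tests, the count of large differences between animals, the tests on interaction genes of liver and hypothalamus, the offset test in fat, and the correlations of splits with the slopes of libraries; the others were set before their results were seen.

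Nuclear oxidative phosphorylation genes stood higher in Gough at E16.5 (median 0.17) and lower at 4 weeks (median -0.24) in the liver. Trends of libraries with GC content and length are a candidate explanation at E16.5, where the offset moved the median to 0.001, whereas at 4 weeks it left -0.211, which argues against these trends as the whole cause. A different number of mitochondria per cell stays open at both ages, with mitochondrial mRNA medians of 0.009 and -0.085. At E16.5 their mean difference was -0.203 ± 0.091 (6 of 13 lower, 0 higher), opposite to what more mitochondria would give, but it was -0.408 ± 0.088 in the hypothalamus, where 0 nuclear genes of the list passed, so a strain difference of the mitochondrial mRNAs themselves could hide a rise. The slopes of the E16.5 libraries on length (log2 per doubling) ran from -0.143 to -0.009 in Gough and from 0.001 to 0.114 in WSB, so that the trend cannot be told apart from strain or from an unknown sequencing batch.

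Some genes varied strongly between Gough animals in both liver and hypothalamus. Tpm3-rs7 and Hmga1b divided several Gough animals. The spread of Gm6563, Eno1b, Gm10260 and 2010315B03Rik came from a single Gough animal each. In liver these were male replicate 2 for Gm6563 (-4.73 log2 CPM) and female replicate 3 for Eno1b (7.16) and Gm10260 (-4.73). For 2010315B03Rik it was female replicate 1 (0.4). In all, 6 genes had large differences between Gough animals shared by both organs while WSB varied little, and 0 had the mirror pattern, but these limits were set after such genes had been seen and so do not show that alleles segregate in the Gough colony. Of the 6 genes 5 shared at least 20% of their sequence, so reads moving between related genes may take part. The count set before leaves such alleles open, with 24 genes following the animal in Gough and 23 in WSB of 9836, against at most 11 (median 3) over 99 mismatched pairings. Of the 27 strain-by-sex genes of these organs 13 could be compared (median r within sex -0.02 in Gough and 0.29 in WSB, with 3 genes above 0.5 in Gough), but in 3 of the 13 the Gough sexes did not overlap in either organ, where a correlation within sex is blind; alleles sampled unequally by sex therefore stay open, as do shared reads for the 7 of 27 that shared at least 20% of their sequence.

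The large strain-by-sex count in fat could reflect epithelial tissue, perhaps of the reproductive tract, in 5 libraries. Without them the count was 217 instead of 969. Removing 5 libraries at random, with the same numbers per group, left 112 to 1394 (median 380.5), above 217 in 15 of 20 removals. Every such removal also took out some of the Gough males high in Epcam. The comparison therefore cannot separate the loss of libraries from the loss of epithelial libraries, and the question stays open. Trends with GC content and length are unlikely as the cause, since the offset raised the count to 1528.

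A less mature liver in Gough embryos was tested as a source of the E16.5 difference, and no clear negative relation was seen across genes. The strain difference had a Spearman rho of 0.19 with the later change of the same 11426 genes within WSB (0.14 and 0.23 for the WSB embryos divided into 4 and 6), where an earlier stage would give a negative value, and -0.07 and 0.18 against the change within Gough. Levels particular to WSB embryos enter both sides of the first comparison and raise its rho. Levels particular to Gough embryos enter the second with opposite signs and lower its rho. A general delay was therefore not shown, but these values cannot exclude it. The embryonic globin genes Hbb-bh1 (76.0 against 8.97 CPM) and Hbb-y (30.9 against 3.53 CPM) were higher in Gough, as an earlier stage would give, so a delay limited to red cells stays open.

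Each count was compared with counts after exchanging labels of animals, the real labels included. For the strain difference the real count was matched by 1 of 100 splits (itself) in every condition, with the highest other counts at 5167, 1, 184, 194 and 847 in the order E16.5, 2-week and 4-week liver, hypothalamus and fat. For sex, 2, 4, 1, 2 and 1 splits reached the real count, with the highest others at 215, 1508, 14, 5258 and 49. For the interaction, 10, 11, 3, 2 and 1 did, with the highest others at 20, 984, 1467, 1579 and 196, so chance is not excluded at E16.5 and at 2 weeks. Exchanging sex within strain also breaks the sex difference itself, so these splits do not test the interaction alone in any condition. Both age counts were reached by 1 of 24 splits (highest others 6 and 212) and the count shared by all conditions by 1 of 100 (highest other 0, edgeR). No strain split exceeded the real count, but 1 or 2 sex splits at E16.5, at 2 weeks and in the hypothalamus, and 1 or 2 interaction splits at 2 weeks, in the 4-week liver and in the hypothalamus, gave more than 100 genes and more than the real ones, which points to a structure of the samples other than sex. In the single split with the highest count, the labels correlated with the GC slope of the libraries for sex at 2 weeks and in the hypothalamus (absolute r 0.72 and 0.69). The same held for the interaction in the 4-week liver and the hypothalamus (absolute r 0.57 and 0.58). Neither GC nor length correlated in this way for the interaction at 2 weeks (0.1 and 0.03) or for sex at E16.5 (-0.19 and -0.09). The highest strain split correlated with the length slope at E16.5 (0.62) and in fat (0.68), where 2 and 3 splits gave more than 100 genes. The length slopes differed by strain at E16.5, and in fat they ran from -0.125 to 0.05 in Gough and from -0.011 to 0.093 in WSB. The overlap of those splits with the real strains was not measured. These correlations therefore cannot show a length structure apart from strain. Each of these correlations describes 1 split picked for its count. The splits of the count shared by all conditions were drawn in each condition separately and so ignore the animals shared by organs.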
